A study of Mus musculus with 20 samples.

How the data were processed

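The libraries are 5C (chromosome conformation capture carbon copy) libraries of mouse V6.5 embryonic stem cells, prepared per the labels' protocols from in situ 3C templates cut with HindIII, with a double alternating primer design over 5 captured regions. In 5C, primers placed at the ends of chosen restriction fragments are joined when the fragments were ligated to each other, so each count belongs to a pair of fragments. Each of the 20 libraries came with 2 kinds of values. The first is raw counts per pair of primers, deposited by the authors without normalization and with pairs of 0 counts left off the list. The second is a balanced contact signal per pair of 4-kb bins within a region, deposited by the authors after binning, smoothing and balancing, per the names of the tables. Reads were mapped with Bowtie to mm9, per the submitters' processing notes. The version, the read filters and the balancing tool are not given in the sources used here. The replicates were deposited separately, not pooled. No molecular identifiers are named in the labels, so the intervals and floors given for single libraries cover counting error only.

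Groups were taken from the labels. LADL cells after 24 h of blue light and dark LADL cells have 5 libraries each, and dark empty-target cells have 3. The lit and dark empty-anchor, lit and dark one-sided, and the 3 groups of the 4-h experiment have 1 library each. The series design describes 5 independent replicate experiments, and the replicate number in the labels was read as the number of that experiment. Replicate 2 was lit at 1.5 mW/cm2 and the other lit libraries at 5 mW/cm2. The titles of the 4-h libraries end in 24hr, while their sample type gives 4 h, which was used. Library depth ranged from 1323505 to 43563409 counts. The 10 libraries of experiments 3 to 5 carry the word monomers in their names and hold 1323505 to 3169199 counts, and the 10 libraries of experiments 1 and 2 and of the 4-h experiment hold 12435130 to 43563409. Each replicated group spans both sets, which were treated as processing batches.

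From the raw counts, pairs of a forward with a reverse primer within the same region and on different fragments were used. This restriction was chosen after the files had been looked at, and all primer orientations were run as an alternative. For each library and region, the expected count at a distance was the mean count per possible primer pair in 40 log-spaced distance classes from 2000 bp upwards, interpolated on log scales. A contact value is log2 of the counts summed over a pair of 20-kb windows divided by the sum expected for the same primer pairs, so 0 is the average contact at that distance. A fragment belongs to a window by its midpoint. The contacts were fixed before the data were examined, as windows around promoters or at stated distances from them: the Zfp462, Klf4 and Rad23b promoters and the SE in the Klf4 region, the Sox2 promoter and its downstream control region, and the Nanog promoter with its upstream enhancer and with the Slc2a3 promoter. The mm9 positions of the transcription starts were written from general knowledge to the nearest kb, after a gene table of another build had been looked at, and were not checked against an mm9 annotation. Contacts of Dppa2 with Dppa4 and of Zfp42 with Triml2, and the Dppa2 viewpoint, were fixed as well and were not analysed here, because those mm9 positions could not be settled.

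Group means of contact values were compared with exact two-sided permutation tests, with Benjamini-Hochberg adjustment within the 3 primary contacts (Zfp462 to SE, Klf4 to SE, Zfp462 to Klf4) and within the 5 comparison contacts, for each comparison of groups. The percentile of a difference was taken among all window pairs at the same distance in the Klf4 region. Differences between single libraries carry exact conditional (Clopper-Pearson) 95% intervals of the count ratio, and no test of the condition. For the map-wide test, counts were summed into 20-kb pixels at least 40 kb apart. The 25669 of 26180 pixels with a mean of at least 10 counts over the 13 replicated libraries were tested with edgeR 4.0.16 (quasi-likelihood test, group as the only factor, offsets from the expected counts), with Benjamini-Hochberg adjustment and a threshold of 0.05. Named pixels are the 5 with the smallest p where none pass, a rule fixed before the data were examined. No mm9 gene annotation was used here, so pixels are named by coordinates and by the fixed windows whose bin they hold. Lists fixed before the data were examined were the pixels that hold 1 of 7 viewpoint bins and all pixels of each region.

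Whether replicate numbers pair the libraries was taken from the series design, which describes replicate experiments. As a check, deviations of pixel values from the group means were correlated between libraries of different groups. The 11 same-numbered pairs gave r from 0.044 to 0.33, and the 44 other pairs from -0.17 to 0.27, so the correlations alone would not establish the pairing. The check was computed after the calls of both fits had been seen. Fits with the replicate number as a block are therefore given beside results whose calls they alter.

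Alternatives planned before the data were examined were a paired test or replicate block, the authors' balanced signal, the mean over primer pairs of log2((count + 1)/(expected + 1)), 12-kb and 40-kb windows or bins, CPM without a distance expectation, leaving out each library in turn, leaving out experiment 2, values within each batch, TMM factors alone and with the block, DESeq2 1.42.0, other count minimums (none, and a mean of 30), limma 3.58.1 on the balanced signal, and only the 2 groups compared. For limma the balanced signal was divided by each library's median over pixels, which departs from the plan, and 0.01 of the overall median was added before log2. Contact values in 12-kb windows had 0.5 added to the observed and the expected count after a window pair with 0 counts was seen. Alternatives chosen after seeing the data were all primer orientations, window positions shifted in 4-kb steps, the block without each pixel's most abundant fragment pair, the block with the balanced signal, the paired test on the balanced signal, the balanced signal without each experiment in turn, the block without each library in turn, and the block for the fixed lists.

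The scripts were tested on simulated data. Counts for the 25669 pixels were drawn from the real means and library sizes, and 200 pixels were changed. Without the block, edgeR recovered 72% of the 2-fold and 39% of the 1.5-fold changes for lit against dark LADL, 60% and 18% for dark LADL against empty target, and 68% and 32% for lit LADL against empty target. With the block, it recovered 86% and 50%, 67% and 42%, and 71% and 33%, in the same order. Unchanged pixels called beside these numbered 8, 6 and 12 without the block and 12, 6 and 8 with it. The counts simulated for the fit without the block held no difference between experiments or batches, so its shares are optimistic, while those for the block kept the mean of each experiment. For pixels called in both comparisons with empty-target cells, 20 sets of counts with no difference between groups and with the means of each experiment were drawn and fitted with the block, and as many pixels of smallest p as in the real lists were compared. A log2 change of 1 planted at the Zfp462 to SE contact was recovered as 0.97 to 1.04 on average over 20 draws for each lit LADL library. Other software was R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.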

Results

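LADL (light-activated dynamic looping) is a synthetic system in which a catalytically inactive Cas9, guided to chosen genomic sites, carries protein anchors that a light-responsive partner can bridge under blue light, so that the chosen sites can be brought together. Contacts were measured in LADL-engineered mouse V6.5 embryonic stem cells, a male line of 129SvJae x C57BL/6 background grown in serum with LIF, and in control cells. The assay was 5C, which counts ligated pairs of HindIII fragments inside captured regions. The 5 regions, in mm9 coordinates, lie around Sox2 (chromosome 3, 33510317 to 35746316), Klf4 (chromosome 4, 53455137 to 57043136), Dppa2 (chromosome 16, 47900556 to 49196555), Nanog (chromosome 6, 122125032 to 122913031) and Zfp42, also called Rex1 (chromosome 8, 44003236 to 45295235). Sox2, Klf4 and Nanog encode transcription factors of the pluripotency network, and Zfp42 and Dppa2 are genes expressed in pluripotent cells.

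The 20 libraries fall into 10 groups. LADL cells were measured after 24 h of blue light (n = 5) and in the dark (n = 5), and empty-target control cells in the dark (n = 3). Empty-anchor cells and one-sided cells were each measured lit and dark with 1 library per condition. A separate experiment has 1 library each of LADL cells after 4 h of light, dark LADL cells and dark empty-target cells. The labels describe LADL and empty-anchor cells as addressed to Klf4 and an element abbreviated SE, and one-sided cells as addressed to the promoter region of Zfp462 alone. Which promoter is joined to the SE in LADL cells is therefore not settled by the labels, and the contacts of Zfp462 with the SE, of Klf4 with the SE and of Zfp462 with Klf4 are all given as primary contacts. The SE was read as the Klf4 enhancer cluster 50 to 70 kb downstream of the Klf4 start, which the labels do not spell out.

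Contacts were read between windows made of whole fragments, in mm9 coordinates. On chromosome 4 they were the promoters of Zfp462 (54949785 to 54968088), which encodes a zinc-finger protein, of Rad23b (55352874 to 55371555), a nucleotide excision repair gene, and of Klf4 (55535132 to 55555904), and the SE (55475247 to 55494277), which lies between Rad23b and Klf4. On chromosome 3 they were the Sox2 promoter (34541860 to 34558642) and its downstream control region (34647235 to 34672093). On chromosome 6 they were the Nanog promoter (122646496 to 122666498), its upstream enhancer (122603068 to 122622624) and the promoter of Slc2a3 (122684879 to 122705038), a glucose transporter gene. The mm9 positions of the transcription starts come from general knowledge and were not checked against an mm9 annotation. A contact value is log2 of observed over expected counts, with 0 the average contact at that distance in the same library and region.

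**Figure D1:**
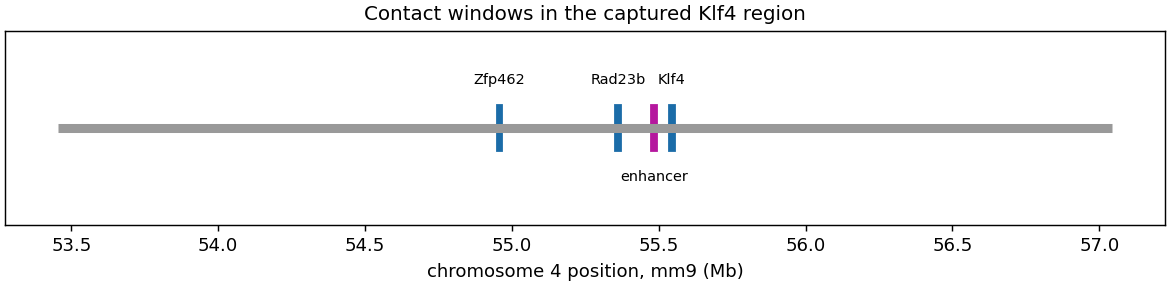
Map of the captured Klf4 region on chromosome 4 (mm9), with the windows of Zfp462, Rad23b, the SE (marked enhancer) and Klf4 drawn to scale along a position axis in Mb. The SE window (55475247 to 55494277) lies between the Rad23b and Klf4 windows.

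Depth ranged from 1323505 to 43563409 counts per library. The 10 libraries of experiments 3 to 5 held 1323505 to 3169199 counts, and the 10 libraries of experiments 1 and 2 and of the 4-h experiment held 12435130 to 43563409. These sets also differ in how the deposited tables are named and were treated as processing batches, and each replicated group spans both. Between 86.7% and 96.5% of the counts joined fragments of the same region. The share was 92.4% ± 4.8 (SD, n = 5) in lit LADL cells, 94.3% ± 2.2 (n = 5) in dark LADL cells (exact two-sided permutation test, p = 0.389) and 94.8% ± 2.5 (n = 3) in empty-target cells. Lit LADL cells had a lower share than dark LADL cells in 4 of 5 experiments (counted after the values were seen). Dark and lit LADL cells each had a lower share than empty-target cells in 3 of the 3 shared experiments. The slope of log count on log distance in the Klf4 region was -0.78 ± 0.032 (SD, n = 5) in lit and -0.79 ± 0.024 (n = 5) in dark LADL cells (exact permutation p = 0.516).

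**Figure D2:**
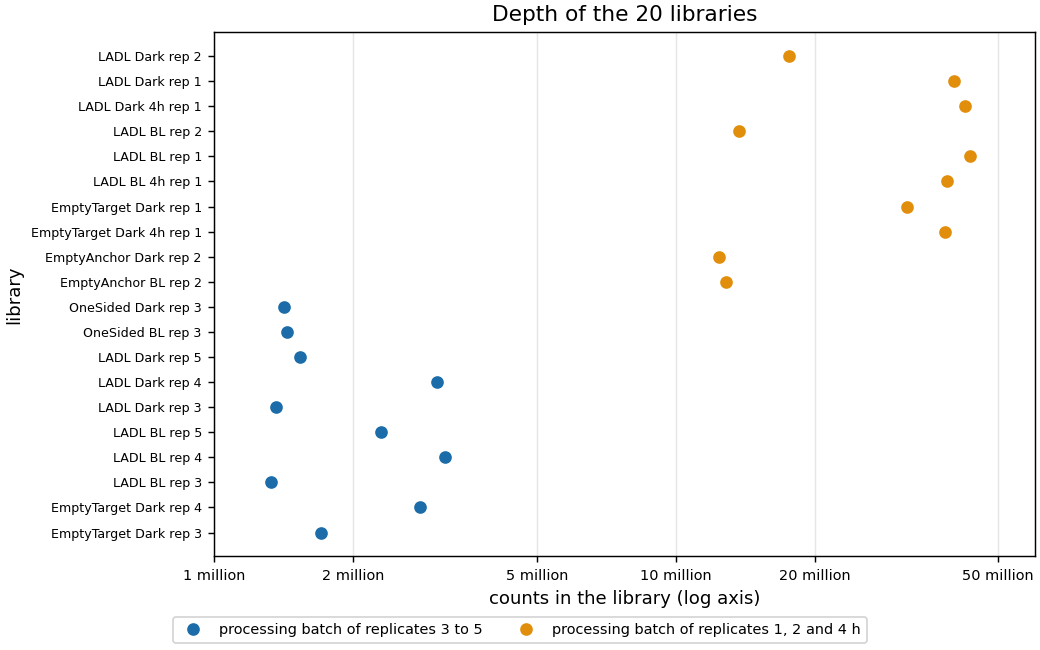
Total counts per library on a log axis, with 1 point per library coloured by processing batch. Libraries of experiments 3 to 5 sit between 1323505 and 3169199 counts, and the others between 12435130 and 43563409.

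The comparison of lit with dark LADL cells asks whether blue light alters contact between the addressed loci. Zfp462 and the SE met more often than the average for their distance both in the light (0.39 ± 0.33, SD, n = 5) and in the dark (0.42 ± 0.25, n = 5). Klf4 and the SE were at 0.30 ± 0.16 lit and 0.36 ± 0.25 dark. Zfp462 and Klf4 met less often than average, at -0.37 ± 0.30 lit and -0.47 ± 0.35 dark. No difference in these 3 contacts exceeded the spread between replicates. Lit minus dark was -0.028 at Zfp462 with the SE (higher in 3 of 5 experiments, exact two-sided permutation p = 0.889), -0.064 at Klf4 with the SE (higher in 1 of 5, exact p = 0.635) and 0.10 at Zfp462 with Klf4 (higher in 4 of 5, exact p = 0.619). The Benjamini-Hochberg adjusted p was 0.889 for each, and the smallest p that 5 against 5 libraries allow is 0.00794. Among all window pairs at the same distance in the Klf4 region, the difference at Zfp462 with the SE lay at the 40.7th percentile of 18823 and that at Klf4 with the SE at the 17.6th percentile of 2641.

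**Figure D3:**
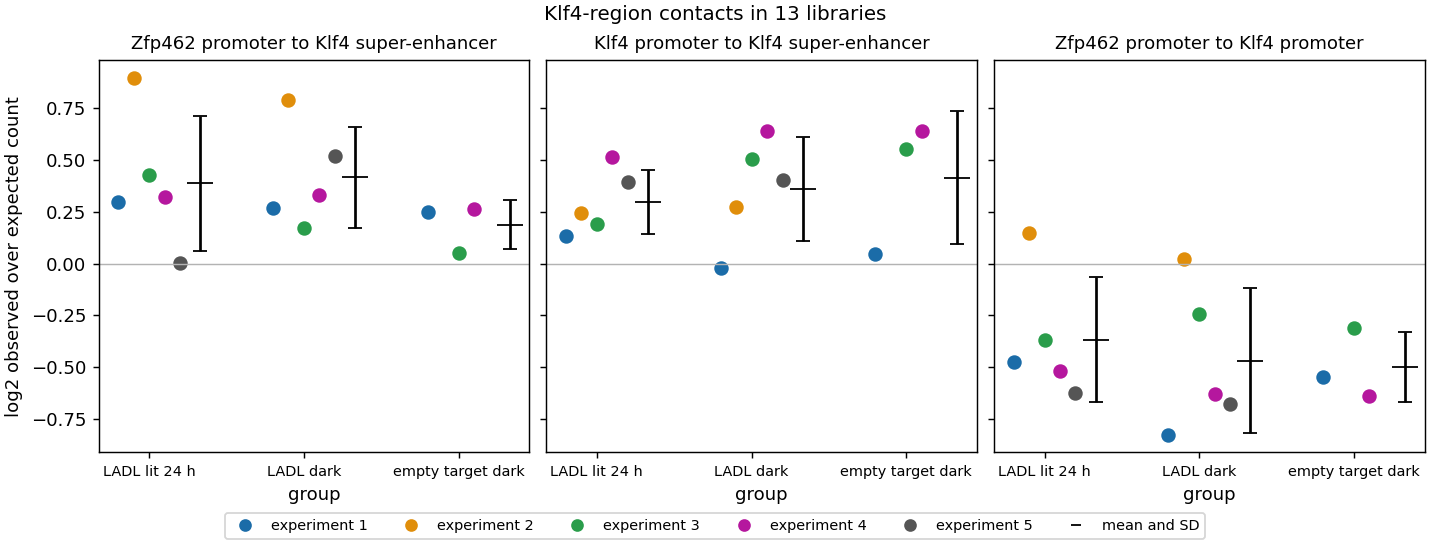
Contact value (log2 observed over expected) of the 3 primary contacts in each library of lit LADL, dark LADL and empty-target cells, coloured by experiment, with the mean and SD of each group beside the points (the SE is drawn as Klf4 super-enhancer). At Zfp462 with the SE, the groups are at 0.39 ± 0.33, 0.42 ± 0.25 and 0.19 ± 0.12.

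Among the comparison contacts, Rad23b with the SE was at 0.30 ± 0.30 (SD, n = 5) lit and 0.13 ± 0.25 (n = 5) dark. The difference of 0.17 lay at the 94.3rd percentile of 5153 window pairs at that distance and was positive in 4 of 5 experiments (exact permutation p = 0.365). It was -0.14 in 12-kb windows and -0.067 in the balanced signal. Without single libraries it lay between 0.096 (without lit LADL replicate 5) and 0.29 (without lit LADL replicate 1), with 0.097 without dark LADL replicate 1. Zfp462 with Rad23b was at 0.31 ± 0.52 lit and 0.24 ± 0.26 dark (difference 0.074, exact p = 0.810, higher in 3 of 5). The Sox2 promoter and its control region stood well above the average for their distance in both states, at 1.00 ± 0.080 lit and 0.94 ± 0.24 dark (difference 0.064, exact p = 0.675, higher in 3 of 5). The Nanog promoter and its upstream enhancer were at 1.27 ± 0.15 lit and 1.3 ± 0.13 dark (difference -0.035, exact p = 0.690, higher in 2 of 5), and Nanog with Slc2a3 at -0.18 ± 0.14 and -0.19 ± 0.17 (difference 0.014, exact p = 0.905, higher in 1 of 5). The adjusted p over these 5 contacts was 0.905 for each (exact two-sided permutation tests). The sign of 7 of the 8 lit minus dark differences turned under at least 1 other setting, and that of Zfp462 with Klf4 when a single library was left out.

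Within experiments 3 to 5, lit minus dark was -0.091 at Zfp462 with the SE (3 against 3 libraries, exact permutation p = 0.6, smallest possible 0.1) and -0.15 at Klf4 with the SE (exact p = 0.4). Within experiments 1 and 2 it was 0.066 (2 against 2, exact p = 0.667, smallest possible 0.333) and 0.064 (exact p = 1), so the sign turned between batches at both contacts and neither batch can reach a p of 0.05. At Zfp462 with Klf4 the within-batch values were 0.013 and 0.24, and at Rad23b with the SE 0.21 and 0.11. In the authors' balanced signal, Zfp462 with the SE was at 0.30 ± 0.27 (SD, n = 5) lit and 0.060 ± 0.37 (n = 5) dark, so that the difference turned to 0.24 (exact permutation p = 0.286, adjusted p = 0.429, higher in 3 of 5 experiments). Experiment 3 alone differed by 1.14 there, and without it the mean was 0.016 (0.24 to 0.35 without each other experiment, chosen after the values were seen). Zfp462 with Klf4 differed by 0.0079 in the balanced signal. Klf4 with the SE was there at 0.090 ± 0.078 lit and 0.24 ± 0.16 dark, with the lit library lower in 5 of 5 experiments. The paired exact sign-flip permutation p was 0.0625, the smallest that 5 pairs allow (adjusted p = 0.188), and this paired test was added because the balanced values had been seen to be lower in every pair.

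**Figure D4:**
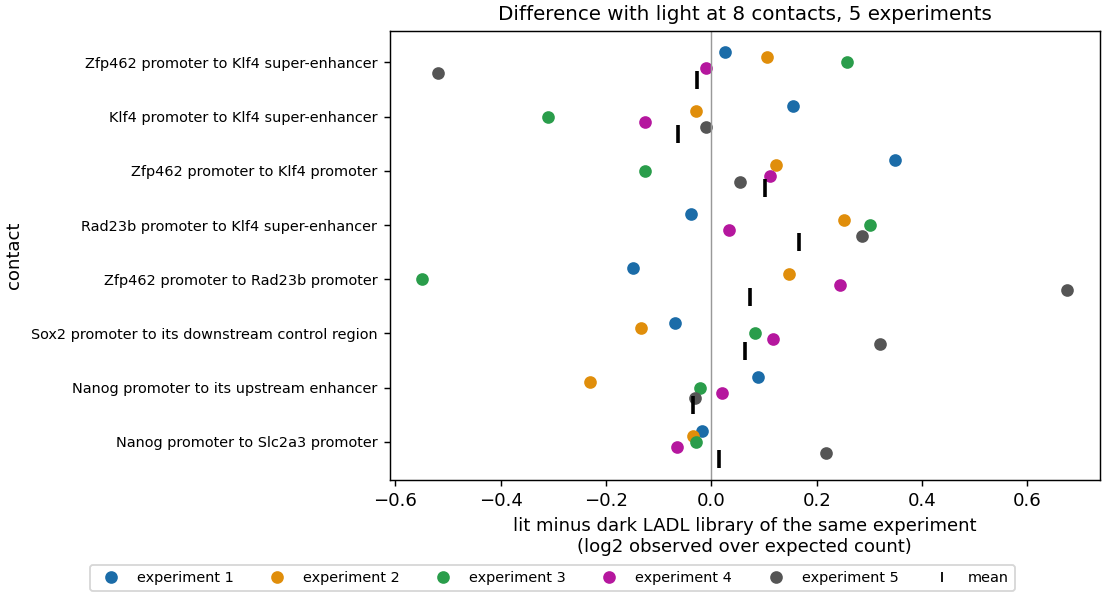
Lit minus dark difference in contact value (log2 observed over expected) at 8 contacts, with 1 point per LADL experiment and a bar for the mean (the SE is drawn as Klf4 super-enhancer). The 5 LADL pairs range from -0.52 to 0.26 at Zfp462 with the SE and from -0.31 to 0.16 at Klf4 with the SE.

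Across all 5 regions, edgeR called 0 of 25669 pixels of 20 kb between lit and dark LADL cells (540 at an unadjusted p under 0.05). DESeq2 called 0 of 25666 (237 at an unadjusted p under 0.05), limma on the balanced signal 0 (749), and edgeR with experiment as a block 0 (1583). Some blocked fits made calls. With TMM factors beside the block, edgeR called 1 pixel, named after its value was seen, 53755137 to 53775136 with 55595137 to 55615136 in the Klf4 region (log2 fold change 0.54 ± 0.11, SE, edgeR adjusted p = 0.0453). The block called 3 pixels without dark LADL replicate 1, 2 without lit LADL replicate 4, 1 each without lit LADL replicate 1 and dark LADL replicate 4, and 0 without each other library. A single fragment pair held 77.4% of the counts of the pixel called with TMM factors, and 38.3% to 91.1% in the pixels called with the block and a library left out. The 5 pixels with the smallest p, none of which passed (edgeR adjusted p = 1.00), lay in the Klf4 and Dppa2 regions. In the Klf4 region, 55135137 to 55155136 with 56455137 to 56475136 was at a log2 fold change of 0.68 ± 0.20 (SE, higher in 5 of 5 experiments). The pair 54655137 to 54675136 with 55155137 to 55175136 was at -0.51 ± 0.15 (higher in 0 of 5), and 55075137 to 55095136 with 56195137 to 56215136 at 0.53 ± 0.15 (higher in 5 of 5). In the Dppa2 region, 48100556 to 48120555 with 49000556 to 49020555 was at -1.53 ± 0.44 (higher in 0 of 5) and 48220556 to 48240555 with 49080556 to 49100555 at -1.76 ± 0.52 (higher in 1 of 5, and -2.82 without lit LADL replicate 1). With all primer orientations the 3 Klf4 pixels were at 0.0077, -0.18 and 0.083 in the order given, and these 2 Dppa2 pixels turned to 0.27 and 0.20. The last was at -1.0 in the balanced signal.

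Of the 175 pixels that hold the SE bin, 119 had a positive lit minus dark fold change, with a median log2 of 0.075. The corresponding counts were 103 of 176 for Zfp462 (median 0.027), 113 of 175 for Klf4 (0.049), 100 of 170 for Rad23b (0.046), 57 of 108 for Sox2 (0.0052), 16 of 35 for Nanog (-0.0016) and 31 of 58 for Zfp42 (0.012). These shifts were not tested, and pixels of 1 viewpoint are not independent. None of the 7 viewpoint lists held a pixel past the threshold over all pixels or adjusted over the list alone (edgeR, smallest list-alone adjusted p = 0.356, at the SE). With experiment as a block, 0 passed over all pixels, and 3 passed when adjusted over the list alone, named here after their values were seen. From the SE bin, 54715137 to 54735136 was at 0.67 ± 0.19 (SE, list-alone edgeR adjusted p = 0.0449, over all pixels 0.420, higher in 4 of 5 experiments) and 54995137 to 55015136 at -0.54 ± 0.13 (list-alone 0.0177, over all 0.361, higher in 0 of 5). From the Zfp42 bin (44383236 to 44403235), 44283236 to 44303235 was at -0.34 ± 0.098 (list-alone edgeR adjusted p = 0.0448, higher in 0 of 5).

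Dark LADL cells were compared with dark empty-target cells to see whether the system alters contacts without light. Zfp462 with the SE was at 0.42 ± 0.25 (SD, n = 5) in dark LADL cells and 0.19 ± 0.12 (n = 3) in empty-target cells. The dark LADL library was higher in 3 of the 3 shared experiments, by 0.019, 0.12 and 0.070. Klf4 with the SE was at 0.36 ± 0.25 and 0.41 ± 0.32, and Zfp462 with Klf4 at -0.47 ± 0.35 and -0.50 ± 0.17. The differences were 0.23 at Zfp462 with the SE (exact two-sided permutation p = 0.179, adjusted p = 0.536), -0.054 at Klf4 with the SE (exact p = 0.786, higher in 0 of 3) and 0.030 at Zfp462 with Klf4 (exact p = 0.875, higher in 2 of 3), the last 2 with an adjusted p of 0.875. None passed, and the smallest p that 5 against 3 libraries allow is 0.0179. At Zfp462 with the SE the mean over the shared experiments was 0.070. The difference was 0.14 without dark LADL replicate 2, whose experiment has no empty-target library. The sign of the other 7 contact differences turned under at least 1 other setting.

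Empty-target cells were at 0.13 ± 0.38 (SD, n = 3) at Rad23b with the SE (dark LADL minus empty target 0.0023, exact permutation p = 0.982, higher in 1 of 3 experiments) and at 0.35 ± 0.28 at Zfp462 with Rad23b (-0.12, exact p = 0.589, higher in 1 of 3). They were at 0.88 ± 0.15 at the Sox2 promoter with its control region (0.053, exact p = 0.732, higher in 3 of 3), at 1.25 ± 0.13 at the Nanog promoter with its enhancer (0.056, exact p = 0.589, higher in 3 of 3) and at -0.27 ± 0.13 at Nanog with Slc2a3 (0.079, exact p = 0.518, higher in 3 of 3, by 0.073, 0.092 and 0.060). The adjusted p of these contacts lay between 0.915 and 0.982 (exact permutation tests), and 3 pairs allow no paired exact p under 0.25. Within experiments 3 to 5, Zfp462 with the SE differed by 0.18 (3 against 2 libraries, exact permutation p = 0.4, smallest possible 0.1) and Klf4 with the SE by -0.081 (exact p = 0.4). In experiments 1 and 2, with 1 empty-target library and so no test, the differences were 0.28 and 0.080.

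Between dark LADL and empty-target cells, edgeR called 0 of 25669 pixels without a block (352 at an unadjusted p under 0.05), DESeq2 0 of 25666 (126) and limma on the balanced signal 0 (1073). With experiment as a block, edgeR called 21 pixels, 20 higher and 1 lower in dark LADL cells (1125 at an unadjusted p under 0.05). Of these, 15 lay in the Klf4 region (15373 of the 25669 pixels), 5 in the Sox2 and 1 in the Zfp42 region. With the block, limma on the balanced signal called 0 (1214), and edgeR called 0 after the most abundant fragment pair of each pixel was left out (1065). The balanced signal was exactly 0 in 148 of the 25669 pixels in empty-target replicate 3 and 57 in replicate 4, and in 0 of the 21 called pixels in any library. The blocked count was 14 without empty-target replicate 4. Of the 20 higher pixels, 17 were higher in 3 of the 3 shared experiments and 3 in 2 of 3. Called pixels of the Sox2 and Zfp42 regions, and 7 of the Klf4 region, are named here after their values were seen. In the Sox2 region they were 33650317 to 33670316 with 35070317 to 35090316 (log2 fold change 0.78 ± 0.11, SE, edgeR adjusted p = 2.40e-06), 34590317 to 34610316 with 35670317 to 35690316 (0.49 ± 0.079), 34610317 to 34630316 with 35590317 to 35610316 (0.52 ± 0.098) and 34010317 to 34030316 with 34910317 to 34930316 (0.50 ± 0.11, higher in 2 of 3 experiments with a paired mean of 0.16). The 1 lower pixel was 33950317 to 33970316 with 34030317 to 34050316 (-0.58 ± 0.11, edgeR adjusted p = 0.000374, higher in 1 of 3 experiments). In the Zfp42 region it was 44683236 to 44703235 with 44783236 to 44803235 (0.59 ± 0.10, edgeR adjusted p = 8.61e-05). The other 2 pixels that were higher in 2 of 3 experiments lay in the Klf4 region. They were 54015137 to 54035136 with 55415137 to 55435136 (0.98, paired mean 0.20) and 54395137 to 54415136 with 55335137 to 55355136 (0.71, paired mean 0.45). Without the most abundant fragment pair the sign of 4 of the 21 turned. They were 3 Sox2 pixels named here, those starting at 34010317 (-0.23), 34610317 (-0.69) and 33950317 (0.018). The fourth was 53835137 to 53855136 with 56455137 to 56475136 in the Klf4 region (-0.11, from 0.61). In 4 of the 21, all in the Klf4 region, the fold stayed within 1 SE of its value without that pair, though the call was lost. These were 54655137 to 54675136 with 56575137 to 56595136 (0.63 ± 0.098 to 0.63 ± 0.13, SE, edgeR adjusted p = 0.130 without the pair) and 54475137 to 54495136 with 55415137 to 55435136 (0.73 ± 0.11 to 0.62 ± 0.16). The others were 53495137 to 53515136 with 54975137 to 54995136 (0.58 ± 0.099 to 0.50 ± 0.13) and 56115137 to 56135136 with 56955137 to 56975136 (0.61 ± 0.11 to 0.50 ± 0.16). A single fragment pair held 41.2% to 97.1% of the counts of each of the 21 pixels, with a median of 60.2%, against a median of 9.29% in pixels not called.

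The 5 pixels with the smallest p without the block did not pass (edgeR adjusted p = 1.00). The pixel of the SE bin (55475137 to 55495136) with 54995137 to 55015136 was at a log2 fold change of 0.72 ± 0.22 (SE, higher in 3 of 3 experiments, and 0.20 with all primer orientations). Also in the Klf4 region, 54775137 to 54795136 with 56015137 to 56035136 was at -1.29 ± 0.35 (higher in 0 of 3, but 0.41 with all primer orientations), 54635137 to 54655136 with 56415137 to 56435136 at -1.58 ± 0.48 (higher in 0 of 3, but -0.18 in the balanced signal and -0.33 there with the block), and 54455137 to 54475136 with 55135137 to 55155136 at 1.14 ± 0.37 (higher in 3 of 3, but -0.19 with all primer orientations). In the Zfp42 region, 44343236 to 44363235 with 44423236 to 44443235 was at -0.46 ± 0.15 (higher in 0 of 3, and -0.21 with all primer orientations, -0.23 in the balanced signal and -0.15 there with the block). The values with all primer orientations carry the limit given for lit against dark LADL cells, since few counts join primers of the same orientation. No viewpoint list held a call without the block. With the block, 1 of the 35 pixels of the Nanog viewpoint passed when adjusted over the list alone and is named after its value was seen: 122605032 to 122625031, the bin of the upstream enhancer, with 122645032 to 122665031, the bin of the promoter (0.21 ± 0.062, list-alone edgeR adjusted p = 0.0242, over all pixels 0.394, higher in 3 of 3).

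Lit LADL cells were compared with dark empty-target cells as the full contrast of system and light. Zfp462 with the SE was at 0.39 ± 0.33 (SD, n = 5) against 0.19 ± 0.12 (n = 3), higher in 3 of 3 shared experiments. Klf4 with the SE was at 0.30 ± 0.16 against 0.41 ± 0.32, and Zfp462 with Klf4 at -0.37 ± 0.30 against -0.50 ± 0.17. The differences were 0.20 at Zfp462 with the SE (exact two-sided permutation p = 0.375), -0.12 at Klf4 with the SE (exact p = 0.482, higher in 1 of 3) and 0.13 at Zfp462 with Klf4 (exact p = 0.607, higher in 2 of 3), each with an adjusted p of 0.607 and with 0.0179 as the smallest possible p. At Zfp462 with the SE the mean over the shared experiments was 0.16, and the difference was 0.074 without lit LADL replicate 2 and 0.13 without empty-target replicate 3. The sign of the other 7 contact differences turned under at least 1 other setting. In the authors' balanced signal the difference at Zfp462 with the SE was 0.44 (exact permutation p = 0.0714, adjusted p = 0.214). Within experiments 3 to 5, Zfp462 with the SE differed by 0.094 (3 against 2 libraries, exact permutation p = 0.6, smallest possible 0.1) and Klf4 with the SE by -0.23 (exact p = 0.2). In experiments 1 and 2 the differences were 0.35 and 0.14, with 1 empty-target library and no test.

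Among the comparison contacts, the Sox2 promoter with its control region differed by 0.12 (exact permutation p = 0.196, adjusted p = 0.833, higher in 2 of 3 experiments). Rad23b with the SE differed by 0.17 (exact p = 0.5, higher in 1 of 3), Zfp462 with Rad23b by -0.044 (exact p = 0.964, higher in 2 of 3), the Nanog promoter with its enhancer by 0.021 (exact p = 0.839, higher in 3 of 3) and Nanog with Slc2a3 by 0.093 (exact p = 0.375, higher in 2 of 3). The Sox2 contact depended on the setting, with -0.16 in the authors' balanced signal (exact permutation p = 0.0179, the smallest possible) and 0.11 in 40-kb windows (exact p = 0.0179). It was 0.20 without empty-target replicate 1 (exact p = 0.0476). None of these passed after adjustment, with 0.0714 as the smallest adjusted p over all alternatives of all contacts.

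Between lit LADL and empty-target cells, edgeR called 0 of 25669 pixels without a block (380 at an unadjusted p under 0.05), DESeq2 0 of 25666 (228) and limma on the balanced signal 0 (1147). With experiment as a block, edgeR called 23 pixels, 22 higher and 1 lower in lit LADL cells (936 at an unadjusted p under 0.05), and 17 lay in the Klf4 region, 3 in the Sox2 region, 2 in the Zfp42 region and 1 in the Dppa2 region. The blocked count was 8 without empty-target replicate 4 and 15 without empty-target replicate 1. It was 1 after the most abundant fragment pair of each pixel was left out (828 at an unadjusted p under 0.05), and limma on the balanced signal called 0 with the block (1193). Both comparisons use the same 3 empty-target libraries and are not independent. Their calls shared 18 pixels, all higher in LADL cells, against 0.017 higher pixels for independent lists. In 20 simulations with no effect the lists of calls were empty but for 1 call in 2 of them, so their shared count says nothing. When the 21 and 23 pixels of smallest p were taken from each simulation instead, a step added after the values were seen, 0 to 7 were shared (median 2). Part of the overlap may come from the shared libraries, which are too few to split. Of the 22 higher pixels, 13 were higher in 3 of the 3 shared experiments, 7 in 2 of 3 and 2 in 1 of 3. Some called pixels are named here after their values were seen. The 2 that were higher in 1 of 3 lay in the Klf4 region. They were 54015137 to 54035136 with 55415137 to 55435136 (log2 fold change 1.08 ± 0.16, SE, edgeR adjusted p = 2.18e-06, paired mean 0.23) and 54395137 to 54415136 with 55335137 to 55355136 (0.86 ± 0.17, paired mean 0.14). Another, 55055137 to 55075136 with 56175137 to 56195136, was at 0.78 ± 0.15 with a paired mean of 0.082 (higher in 2 of 3). The 1 lower pixel, in the Klf4 region, was 56815137 to 56835136 with 56915137 to 56935136 (log2 fold change -0.31 ± 0.065, SE, edgeR adjusted p = 0.00497, higher in 0 of 3), and it is the pixel that passed without the most abundant fragment pair (-0.33 ± 0.065, edgeR adjusted p = 0.0275). In the Sox2 region, 34590317 to 34610316 with 35670317 to 35690316 was at 0.43 ± 0.080, 34010317 to 34030316 with 34910317 to 34930316 at 0.60 ± 0.12 (higher in 2 of 3, paired mean 0.12) and 34610317 to 34630316 with 35590317 to 35610316 at 0.46 ± 0.098. In the Zfp42 region, 44683236 to 44703235 with 44783236 to 44803235 was at 0.46 ± 0.10. In the Dppa2 region, 48360556 to 48380555 with 48800556 to 48820555 was at 0.31 ± 0.074 (edgeR adjusted p = 0.0439, higher in 2 of 3, paired mean 0.18). Without the most abundant fragment pair the sign of 4 of the 23 turned. They were the Sox2 pixels starting at 34010317 (-0.26) and 34590317 (-0.068) and the Zfp42 pixel starting at 44683236 (-0.18). The fourth was 53835137 to 53855136 with 56455137 to 56475136 in the Klf4 region (-0.21, from 0.37). In 4 of the 23, all in the Klf4 region, the fold stayed within 1 SE of its value. Besides the 1 lower pixel these were 54475137 to 54495136 with 55415137 to 55435136 (0.63 ± 0.12 to 0.54 ± 0.16, SE), 54755137 to 54775136 with 55235137 to 55255136 (0.42 ± 0.091 to 0.35 ± 0.10) and 54655137 to 54675136 with 56575137 to 56595136 (0.42 ± 0.098 to 0.38 ± 0.13), whose calls were lost.

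The 5 pixels with the smallest p without the block did not pass there (edgeR adjusted p = 1.00). In the Zfp42 region, 44643236 to 44663235 with 44963236 to 44983235 was at a log2 fold change of 0.37 ± 0.11 (SE, higher in 2 of 3 experiments) and passed with the block (0.33 ± 0.066, edgeR adjusted p = 0.00282), though not with TMM factors beside the block (0.29, edgeR adjusted p = 0.181) or without its most abundant fragment pair (0.17, edgeR adjusted p = 1). It was -0.17 with all primer orientations and -0.045 in the balanced signal. In the Sox2 region, 34330317 to 34350316 with 34610317 to 34630316 was at 0.67 ± 0.18 (higher in 3 of 3, and 0.32 with all primer orientations). In the Klf4 region, 53795137 to 53815136 with 56915137 to 56935136 was at -1.11 ± 0.27 (-0.47 in the balanced signal and -0.35 there with the block), 56415137 to 56435136 with 56535137 to 56555136 at -0.87 ± 0.23 (0.65 with all primer orientations) and 54375137 to 54395136 with 56595137 to 56615136 at -0.83 ± 0.26 (-0.54 with the block and -0.24 with all primer orientations), each higher in 0 of 3. The limit given above for values with all primer orientations applies to these pixels as well. No viewpoint list held a call, with or without the block.

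The remaining groups have 1 library each, so their differences carry counting intervals and no test of the condition. Each difference was also computed under 4 other settings (12-kb windows, 40-kb windows, the mean over primer pairs and the authors' balanced signal), or 3 at Nanog with Slc2a3, and their range is given beside it. In empty-anchor cells, Zfp462 with the SE was at 0.58 lit and 0.42 dark, a difference of 0.16 (exact 95% interval -0.057 to 0.37, other settings 0.081 to 0.31), and Klf4 with the SE differed by 0.11 (0.00057 to 0.23, other settings -0.046 to 0.12). The largest light difference of these cells among the 8 contacts was 0.57 at Zfp462 with Rad23b (0.23 to 0.91, other settings 0.21 to 0.64), the 98.6th percentile of 15325 window pairs at that distance. Zfp462 with the SE lay at the 76.6th of 18823 and Klf4 with the SE at the 86.9th of 2641. The interval also lay above 0 at the Sox2 promoter with its control region (0.11, 3.7e-05 to 0.22, other settings -0.21 to 0.075).

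The LADL pair of the same experiment, also lit at 1.5 mW/cm2, differed by 0.11 at Zfp462 with the SE (exact 95% interval -0.065 to 0.28, other settings -0.065 to 0.24) and by -0.028 at Klf4 with the SE (-0.13 to 0.073, other settings -0.29 to -0.048). Its interval lay above 0 at Rad23b with the SE (0.25, 0.039 to 0.46, other settings -0.052 to 0.22). It lay below 0 at the Sox2 contact (-0.13, -0.24 to -0.027, other settings -0.33 to -0.0032) and at the Nanog promoter with its enhancer (-0.23, -0.29 to -0.17, other settings -0.26 to -0.13). Among window pairs at the same distance, Zfp462 with the SE lay at the 64.2nd percentile, Klf4 with the SE at the 39.6th and Rad23b with the SE at the 92.2nd.

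In dark empty-anchor cells the contact value was below that of dark LADL cells of that experiment at Zfp462 with the SE (-0.37, exact 95% interval -0.57 to -0.18, other settings -0.49 to -0.18) and Klf4 with the SE (-0.28, -0.39 to -0.18, other settings -0.33 to -0.12). The same held at Zfp462 with Klf4 (-0.39, -0.67 to -0.12, other settings -0.58 to -0.26) and Zfp462 with Rad23b (-0.73, -1.05 to -0.42, other settings -0.62 to -0.17). Empty-anchor cells were also below at contacts that were not addressed, Nanog with Slc2a3 (-0.25, -0.36 to -0.14, other settings -0.39 to -0.14) and the Sox2 contact (-0.11, -0.21 to -0.0080, other settings -0.14 to -0.0066). At the Nanog promoter with its enhancer they were above (0.089, 0.034 to 0.14), though the other settings ran from -0.077 to 0.071. Among window pairs at the same distance in the Klf4 region, low values were common between these 2 libraries. Zfp462 with the SE lay at the 16.5th percentile of 18823 and Zfp462 with Klf4 at the 15.7th of 20486, against the 2.42nd of 2641 at Klf4 with the SE and the 2.92nd of 15325 at Zfp462 with Rad23b. The slope of log count on log distance was -0.80 in the dark empty-anchor and -0.77 in the dark LADL library.

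In one-sided cells, Zfp462 with the SE had 32 counts lit and 32 dark, and the light difference of -0.049 (exact 95% interval -0.80 to 0.70, other settings -0.082 to 0.52) leaves a change of 1.5-fold undetectable at this depth. Klf4 with the SE differed by -0.021 (-0.33 to 0.29, other settings -0.074 to 0.068). Dark one-sided minus dark LADL cells of the same experiment was -0.087 at Zfp462 with the SE (-0.84 to 0.67, other settings -0.65 to 0.46) and -0.25 at Klf4 with the SE (-0.56 to 0.049, other settings -0.39 to -0.018). The intervals of the other 6 contacts also held 0. Among window pairs at the same distance, the light difference lay at the 43.9th percentile at Zfp462 with the SE and the 46.1st at Klf4 with the SE, and the dark difference at the 38.7th and 8.60th.

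After 4 h of light, Zfp462 with the SE was at 0.40 against 0.36 in the dark, a difference of 0.039 (exact 95% interval -0.079 to 0.16, other settings 0.032 to 0.26). Klf4 with the SE differed by 0.083 (0.024 to 0.14, other settings -0.052 to 0.17) and Rad23b with the SE by 0.16 (0.041 to 0.29, other settings -0.041 to 0.15). The intervals also lay above 0 at the Sox2 promoter with its control region (0.31, 0.25 to 0.37, other settings 0.22 to 0.35) and at Nanog with Slc2a3 (0.19, 0.12 to 0.26, other settings -0.00046 to 0.23). The Nanog promoter with its enhancer differed by 0.060 (0.025 to 0.094, other settings -0.096 to 0.082) and Zfp462 with Rad23b by -0.30 (-0.47 to -0.12, other settings -0.33 to -0.076). Among window pairs at the same distance, Zfp462 with the SE lay at the 58.1st percentile, Klf4 with the SE at the 81.3rd, Rad23b with the SE at the 90.4th and Zfp462 with Rad23b at the 4.77th.

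Against the empty-target library of the 4-h experiment, the dark LADL library differed by 0.12 at Zfp462 with the SE (exact 95% interval -0.0022 to 0.24, other settings -0.087 to 0.12) and by -0.26 at Nanog with Slc2a3 (-0.33 to -0.19, other settings -0.23 to -0.081). It differed by 0.24 at Zfp462 with Rad23b (0.062 to 0.41, other settings 0.097 to 0.29), -0.086 at the Sox2 contact (-0.15 to -0.024, other settings -0.11 to 0.014) and -0.057 at the Nanog promoter with its enhancer (-0.091 to -0.022, other settings -0.056 to 0.058). The lit LADL library differed from it by 0.16 at Zfp462 with the SE (0.035 to 0.28, other settings -0.024 to 0.38), 0.14 at Klf4 with the SE (0.082 to 0.21, other settings -0.081 to 0.31) and 0.29 at Rad23b with the SE (0.16 to 0.42, other settings -0.12 to 0.26). It differed by 0.22 at the Sox2 contact (0.16 to 0.28, other settings 0.11 to 0.30) and -0.071 at Nanog with Slc2a3 (-0.13 to -0.0062, other settings -0.23 to 0.15). Among window pairs at the same distance, dark LADL minus empty target lay at the 75.8th percentile at Zfp462 with the SE and the 91.2nd at Zfp462 with Rad23b. Lit LADL minus empty target lay at the 81.2nd at Zfp462 with the SE, the 90.6th at Klf4 with the SE and the 96.9th at Rad23b with the SE. Counting intervals leave out any spread between cultures. At Zfp462 with the SE the paired differences over the 5 LADL experiments ran from -0.52 to 0.26, with an SD of 0.29 against 0.23 expected from counting alone.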

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

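Pixel differences of single libraries were looked at after these pixels had been picked for their lit minus dark difference in LADL cells, and none of the differences between cell types given here was tested.

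Primers of the same orientation should not form a product in 5C, so the share of counts that join them is a measure of noise. LADL replicate 1 stood far from the other libraries of its group, both lit, with 1.75% of counts against 0.0030% to 0.24%, and dark, with 0.743% against 0.0027% to 0.126%. A high share was not particular to these libraries. Empty-target replicate 1 of the same experiment held 1.01%, and the 4-h experiment held 0.803% in lit LADL, 1.13% in dark LADL and 1.00% in empty-target cells. Over 26 sets of values looked at in this way, 2 had such a library, and about 1 in 20 is found by chance. These counts were left out of the contact values.

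At 4 of the pixels named for lit against dark LADL cells, all 5 LADL experiments moved 1 way and at least 1 pair of control or 4-h libraries moved the other way. In the Klf4 region, 55135137 to 55155136 with 56455137 to 56475136 had a mean paired lit minus dark log2 difference of 0.68 in LADL cells, against -0.21 in empty-anchor cells, -0.024 in one-sided cells and -0.32 after 4 h of light. The pair 54655137 to 54675136 with 55155137 to 55175136 was at -0.51 in LADL cells and 0.027 in empty-anchor cells, against -0.47 in one-sided cells and -0.41 after 4 h, which have the sign of LADL cells. The pair 55075137 to 55095136 with 56195137 to 56215136 was at 0.59 in LADL cells, 0.14 in empty-anchor cells, -0.35 in one-sided cells and -0.20 after 4 h. In the Dppa2 region, 48100556 to 48120555 with 49000556 to 49020555 was at -1.63 in LADL cells, -0.029 in empty-anchor cells, 1.56 in one-sided cells and 0.60 after 4 h. With all primer orientations its lit minus dark log2 fold change in LADL cells is given as 0.27, which the few added counts hardly explain. None of these pixels passed the threshold in LADL cells, so no explanation is weighed.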

How the results depend on the processing

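Alternatives chosen after seeing the data are all primer orientations, shifted windows, the balanced signal without each experiment, paired tests of the balanced signal, and the block applied without the most abundant fragment pair, to the balanced pixels, without each library in turn and to the fixed lists. No contact passed its test in any of the 469 alternative values, with 0.0714 as the smallest adjusted p (exact permutation tests). This is no measure of stability, since 80 of these tests cannot give a p under 0.05 at all and 326, these included, cannot pass after adjustment when only 1 contact of its set reaches the smallest p. Apart from leaving out single libraries, 192 alternative contact values kept their sign and 76 turned it, and when single libraries were left out 176 kept it and 32 turned it. These sign counts also hold 7 values that have no adjusted p and are not among the 469, the lowest and the highest of the shifted window pairs and the balanced signal without each of the 5 experiments. For each contact, pixel and count given here, the cause was not tested. The block changed no other call of a contact, pixel or list than those given. Alternatives that could not be run were 40-kb windows for Nanog with Slc2a3, whose windows overlap, and all alternatives of the Dppa2 with Dppa4 and Zfp42 with Triml2 contacts and the Dppa2 viewpoint, which were not analysed here. Depth limits the contacts of experiments 3 to 5, where Zfp462 with the SE rests on 32 to 73 counts per LADL library, against 516 to 1135 in experiments 1 and 2. In 12-kb windows, Zfp462 with Klf4 has 0 counts in dark LADL replicate 5, so differences of dark LADL cells there rest on the 0.5 counts added. Pixel counts of 0 at 5 against 3 libraries have limited reach, as the simulated shares without the block show.

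With 12-kb windows, lit minus dark was 0.0048 at Klf4 with the SE, -0.14 at Rad23b with the SE and 0.029 at Nanog with its enhancer. For dark LADL minus empty target it was 0.063 at Klf4 with the SE, -0.74 at Zfp462 with Klf4, 0.13 at Zfp462 with Rad23b and -0.27 at Sox2 with its control region. For lit LADL minus empty target it was 0.068 at Klf4 with the SE, -0.14 at Rad23b with the SE, 0.15 at Zfp462 with Rad23b and -0.20 at Sox2 with its control region. With 40-kb windows, dark LADL minus empty target was -0.0082 at Zfp462 with Klf4 and 0.047 at Zfp462 with Rad23b. Lit LADL minus empty target there was 0.047 at Zfp462 with Rad23b. In the authors' balanced signal, lit minus dark was 0.24 at Zfp462 with the SE, -0.067 at Rad23b with the SE, -0.15 at Zfp462 with Rad23b, -0.017 at Sox2 with its control region, 0.0050 at Nanog with its enhancer and -0.13 at Nanog with Slc2a3. For dark LADL minus empty target it was 0.011 at Klf4 with the SE, -0.025 at Zfp462 with Klf4, -0.074 at Rad23b with the SE, -0.15 at Sox2 with its control region and -0.075 at Nanog with Slc2a3. For lit LADL minus empty target it was -0.017 at Zfp462 with Klf4, -0.14 at Rad23b with the SE, -0.16 at Sox2 with its control region and -0.21 at Nanog with Slc2a3. With the mean over primer pairs, lit minus dark was 0.0018 at Zfp462 with the SE. Dark LADL minus empty target there was -0.028 at Zfp462 with Klf4 and -0.013 at Rad23b with the SE. Lit LADL minus empty target there was 0.043 at Zfp462 with Rad23b and -0.015 at Nanog with its enhancer. As CPM of the region, dark LADL minus empty target was -0.026 at Zfp462 with Klf4, -0.045 at Rad23b with the SE, -0.0041 at Sox2 with its control region and -0.00097 at Nanog with its enhancer. For lit LADL minus empty target it was -0.025 at Nanog with its enhancer. As paired differences with experiment as the block, dark LADL minus empty target was -0.065 at Zfp462 with Klf4 and -0.035 at Rad23b with the SE. As paired differences (block) of the balanced signal, lit minus dark was, by construction, again 0.24 at Zfp462 with the SE, -0.067 at Rad23b with the SE, -0.15 at Zfp462 with Rad23b, -0.017 at Sox2 with its control region, 0.0050 at Nanog with its enhancer and -0.13 at Nanog with Slc2a3. For dark LADL minus empty target it was -0.15 at Zfp462 with Klf4, -0.19 at Rad23b with the SE, -0.16 at Sox2 with its control region and -0.032 at Nanog with Slc2a3. For lit LADL minus empty target it was -0.021 at Zfp462 with Klf4, -0.13 at Rad23b with the SE, -0.16 at Sox2 with its control region and -0.27 at Nanog with Slc2a3. Within experiments 3 to 5, dark LADL minus empty target was -0.040 at Zfp462 with Klf4. Lit LADL minus empty target there was -0.027 at Zfp462 with Klf4. Within experiments 1 and 2, lit minus dark was 0.066 at Zfp462 with the SE, 0.064 at Klf4 with the SE, -0.0012 at Zfp462 with Rad23b, -0.10 at Sox2 with its control region and -0.026 at Nanog with Slc2a3. For dark LADL minus empty target it was 0.080 at Klf4 with the SE and 0.37 at Zfp462 with Rad23b. For lit LADL minus empty target it was 0.14 at Klf4 with the SE, 0.37 at Zfp462 with Rad23b and -0.012 at Sox2 with its control region. With experiment 2 left out, lit minus dark was 0.014 at Nanog with its enhancer. Dark LADL minus empty target there was -0.093 at Zfp462 with Klf4 and -0.0066 at Sox2 with its control region. At the highest of the shifted window pairs, lit minus dark was 0.26 at Zfp462 with the SE. Without experiments 1 to 5 in turn, lit minus dark at Zfp462 with the SE in the balanced signal was 0.27, 0.24, 0.016, 0.35 and 0.33.

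Leaving out each library in turn gave the following ranges. Lit minus dark ranged over -0.16 to 0.069 at Zfp462 with the SE, -0.16 to 0.0062 at Klf4 with the SE, -0.026 to 0.23 at Zfp462 with Klf4, 0.096 to 0.29 at Rad23b with the SE, -0.039 to 0.27 at Zfp462 with Rad23b, -0.032 to 0.12 at Sox2 with its control region, -0.089 to 0.018 at Nanog with its enhancer and -0.034 to 0.068 at Nanog with Slc2a3. Dark LADL minus empty target ranged over 0.14 to 0.29 at Zfp462 with the SE, -0.24 to 0.060 at Klf4 with the SE, -0.093 to 0.12 at Zfp462 with Klf4, -0.13 to 0.22 at Rad23b with the SE, -0.27 to 0.0014 at Zfp462 with Rad23b, -0.0066 to 0.15 at Sox2 with its control region, -0.015 to 0.11 at Nanog with its enhancer and 0.020 to 0.15 at Nanog with Slc2a3. Lit LADL minus empty target ranged over 0.074 to 0.30 at Zfp462 with the SE, -0.30 to -0.0036 at Klf4 with the SE, 0.0036 to 0.23 at Zfp462 with Klf4, 0.036 to 0.39 at Rad23b with the SE, -0.20 to 0.16 at Zfp462 with Rad23b, 0.062 to 0.20 at Sox2 with its control region, -0.050 to 0.075 at Nanog with its enhancer and 0.034 to 0.16 at Nanog with Slc2a3.

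Differences of single libraries that lay outside their counting interval under another setting are given by setting, over 8 pairs of libraries. No value is given where a library has 0 counts, as at Zfp462 with Klf4 in 12-kb windows, with 4 counts in lit and 0 in dark one-sided cells. With 12-kb windows, lit minus dark empty-anchor cells came to -0.046 at Klf4 with the SE, -0.17 at Sox2 with its control region, 0.34 at Nanog with its enhancer and 0.077 at Nanog with Slc2a3. 4-h lit minus dark LADL came to 0.43 at Zfp462 with Klf4, -0.041 at Rad23b with the SE, 0.22 at Sox2 with its control region and -0.00046 at Nanog with Slc2a3. Lit minus dark LADL of experiment 2 came to -0.065 at Zfp462 with the SE, -0.052 at Rad23b with the SE and -0.33 at Sox2 with its control region. Dark empty-anchor minus dark LADL came to -0.17 at Zfp462 with Rad23b, -0.059 at Nanog with its enhancer and -0.39 at Nanog with Slc2a3. Dark one-sided minus dark LADL came to 0.43 at Sox2 with its control region. 4-h dark LADL minus empty target came to -0.087 at Zfp462 with the SE, 0.15 at Klf4 with the SE, 0.47 at Zfp462 with Klf4 and 0.058 at Nanog with its enhancer. 4-h lit LADL minus empty target came to -0.024 at Zfp462 with the SE, 0.89 at Zfp462 with Klf4, 0.11 at Rad23b with the SE, 0.11 at Sox2 with its control region, 0.13 at Nanog with its enhancer and -0.23 at Nanog with Slc2a3. With 40-kb windows, lit minus dark empty-anchor cells came to 0.21 at Zfp462 with Rad23b. 4-h lit minus dark LADL came to -0.022 at Klf4 with the SE, -0.14 at Zfp462 with Klf4, -0.076 at Zfp462 with Rad23b and 0.25 at Sox2 with its control region. Lit minus dark LADL of experiment 2 came to -0.0032 at Sox2 with its control region and -0.16 at Nanog with its enhancer. Dark empty-anchor minus dark LADL came to -0.12 at Klf4 with the SE. 4-h dark LADL minus empty target came to -0.034 at Klf4 with the SE, 0.12 at Zfp462 with Klf4 and 0.014 at Sox2 with its control region. 4-h lit LADL minus empty target came to -0.056 at Klf4 with the SE and 0.092 at Rad23b with the SE. In the authors' balanced signal, lit minus dark empty-anchor cells came to 0.087 at Nanog with its enhancer and 0.029 at Nanog with Slc2a3. Lit minus dark one-sided cells came to -0.79 at Zfp462 with Klf4 and 0.41 at Sox2 with its control region. 4-h lit minus dark LADL came to -0.052 at Klf4 with the SE, -0.030 at Rad23b with the SE and -0.096 at Nanog with its enhancer. Lit minus dark LADL of experiment 2 came to -0.29 at Klf4 with the SE, -0.28 at Zfp462 with Klf4 and -0.13 at Nanog with its enhancer. Dark empty-anchor minus dark LADL came to -0.23 at Zfp462 with Rad23b, 0.0071 at Nanog with its enhancer and -0.14 at Nanog with Slc2a3. Dark one-sided minus dark LADL came to 0.71 at Zfp462 with Klf4 and 0.085 at Nanog with Slc2a3. 4-h dark LADL minus empty target came to -0.033 at Zfp462 with the SE, -0.029 at Klf4 with the SE, -0.093 at Rad23b with the SE and -0.081 at Nanog with Slc2a3. 4-h lit LADL minus empty target came to -0.081 at Klf4 with the SE, -0.18 at Zfp462 with Klf4, -0.12 at Rad23b with the SE, 0.29 at Sox2 with its control region, -0.15 at Nanog with its enhancer and 0.15 at Nanog with Slc2a3. With the mean over primer pairs, lit minus dark empty-anchor cells came to -0.21 at Sox2 with its control region and 0.10 at Nanog with its enhancer. 4-h lit minus dark LADL came to 0.26 at Zfp462 with the SE, 0.17 at Klf4 with the SE and -0.092 at Zfp462 with Klf4. Dark empty-anchor minus dark LADL came to -0.18 at Zfp462 with the SE, -0.0066 at Sox2 with its control region and -0.077 at Nanog with its enhancer. 4-h dark LADL minus empty target came to 0.14 at Klf4 with the SE and -0.18 at Nanog with Slc2a3. 4-h lit LADL minus empty target came to 0.38 at Zfp462 with the SE, 0.31 at Klf4 with the SE, -0.17 at Zfp462 with Klf4, 0.30 at Sox2 with its control region, 0.053 at Nanog with its enhancer and 0.0071 at Nanog with Slc2a3.

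Without the block, every alternative of the pixel test gave 0 calls in the 3 comparisons. At an unadjusted p under 0.05 stood 569, 372 and 404 pixels without a low-count filter (lit against dark LADL, dark LADL against empty target, lit LADL against empty target). There were 121, 56 and 99 in 40-kb bins and 428, 237 and 438 with TMM factors. With the block, edgeR called 0, 21 and 23 pixels in the same order. By region, 15 of the dark LADL and 17 of the lit LADL calls against empty target lay in the Klf4 region, 5 and 3 in the Sox2 region and 1 and 2 in the Zfp42 region, both over all pixels and adjusted over the list alone. The Dppa2 region held 1 of the lit LADL calls over all pixels and 0 adjusted over the list alone. Adjusted over the list alone, the block gave 2 calls at the SE viewpoint and 1 at the Zfp42 viewpoint for lit against dark LADL cells and 1 at the Nanog viewpoint for dark LADL against empty-target cells. The block with TMM factors gave 1, 18 and 22 calls, and the block without the most abundant fragment pair gave 0, 0 and 1.

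With the block and 1 library left out, calls of dark LADL against empty-target cells came to 22 without empty-target replicate 1, 24 without empty-target replicate 3 and 14 without empty-target replicate 4. They came to 20, 26, 22, 15 and 22 without dark LADL replicates 1, 2, 3, 4 and 5. Calls of lit LADL against empty-target cells came to 15, 18 and 8 without empty-target replicates 1, 3 and 4, and to 24, 24, 22, 23 and 23 without lit LADL replicates 1 to 5. Calls of lit against dark LADL cells came to 1 without lit LADL replicate 1, 2 without lit LADL replicate 4, 3 without dark LADL replicate 1 and 1 without dark LADL replicate 4, and 0 without each of the others. These pixels, named after their values were seen, were 4 in the Klf4 and Sox2 regions besides the 1 called with TMM factors. The TMM pixel, 53755137 to 53775136 with 55595137 to 55615136 in the Klf4 region, was at 0.54 ± 0.11 (SE, edgeR adjusted p = 0.0453), at 0.53 without lit LADL replicate 4 and at 0.58 without dark LADL replicate 4. In the same region, 55055137 to 55075136 with 56175137 to 56195136 was at 0.54 without lit LADL replicate 1 and 0.74 without dark LADL replicate 1, and 53835137 to 53855136 with 56455137 to 56475136 at -0.32 without lit LADL replicate 4. In the Sox2 region, without dark LADL replicate 1, 33950317 to 33970316 with 34030317 to 34050316 was at 0.44 and 34310317 to 34330316 with 34670317 to 34690316 at 0.76.

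Apart from leaving out single libraries, the pixels named for their small p kept their sign and their side of the threshold in 167 alternative values, turned sign in 7 and passed in 1. The sign turns with all primer orientations carry the limit given with the pixels of lit against dark LADL cells. With all primer orientations, lit minus dark LADL was 0.27 and 0.20 at the Dppa2-region pixels 48100556 to 48120555 with 49000556 to 49020555 and 48220556 to 48240555 with 49080556 to 49100555. Dark LADL minus empty target was then 0.41 at 54775137 to 54795136 with 56015137 to 56035136 and -0.19 at 54455137 to 54475136 with 55135137 to 55155136 in the Klf4 region. Lit LADL minus empty target was then 0.65 at 56415137 to 56435136 with 56535137 to 56555136 in the Klf4 region and -0.17 at 44643236 to 44663235 with 44963236 to 44983235 in the Zfp42 region. This Zfp42-region pixel was at -0.045 in the balanced signal (limma), passed with the block at 0.33 and passed with the block without 6 of the 8 libraries left out in turn. It did not pass with the block without lit LADL replicate 1 (0.24, edgeR adjusted p = 0.322) or empty-target replicate 1 (0.062, 0.999), with TMM factors (0.29, 0.181) or without its most abundant fragment pair (0.17, 1). The Sox2-region pixel 34330317 to 34350316 with 34610317 to 34630316 passed with the block without lit LADL replicate 1 (0.70) and without lit LADL replicate 2 (0.59).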

Other observations

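The tests of a library-wide contrast, of shifted windows and of the counting spread, and the block without the most abundant fragment pair with the folds kept there, were chosen after the results were seen. Klf4 with the SE stood at different values in the 2 processing batches, and this difference was not tested. In experiments 3 to 5 it was at 0.52 ± 0.12 (SD, n = 3) in dark LADL cells, 0.37 ± 0.16 (n = 3) in lit LADL cells and 0.60 ± 0.062 (n = 2) in empty-target cells. In experiments 1 and 2 it was at 0.13 ± 0.21 (n = 2) in dark and 0.19 ± 0.077 (n = 2) in lit LADL cells, and at 0.047 in the 1 empty-target library. Zfp462 with the SE was at 0.90 lit and 0.79 dark in LADL experiment 2, against 0.00069 to 0.52 in the other LADL experiments. In the authors' balanced signal, bin pairs at 0 numbered 165741 in empty-target replicate 3, 141784 in lit LADL replicate 5, 103826 in empty-target replicate 4, 29146 in lit LADL replicate 4, 24598 in dark LADL replicate 2 and 5042 in lit LADL replicate 1, and the reason was not examined.

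The libraries were regrouped into sets of the same sizes and the pixels called again with edgeR. Without the block, the real groups gave 0 pixels in each of the 3 comparisons. Any split reaches a count of 0, as the 75 drawn for lit against dark LADL cells and the 56 of each of the other comparisons do, so these counts say nothing about chance. Other splits gave up to 1671 pixels for lit against dark LADL cells, 789 for dark LADL against empty-target cells and 1543 for lit LADL against empty-target cells. In the last 2 comparisons these splits set experiments 3 to 5 against experiments 1 and 2, which is the processing batch, and in the first they differ from it by 1 library. Such counts point to a structure of the samples. Splits that part as many experiments as the real groups do, 8 in each comparison, gave at most 0 pixels, while the others keep libraries of 1 experiment together.

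With experiment as a block, the real groups gave 0, 21 and 23 pixels. For lit against dark LADL cells the real count of 0 is again reached by any split, here 60, and other splits gave up to 6 pixels (up to 2 among those that part all 5 experiments). For dark LADL against empty-target cells the highest other split gave 20, and for lit LADL against empty-target cells 14, with the real split as the only 1 of 56 to reach its own count. Most of the 56 splits keep libraries of an experiment together, unlike the real groups. The 8 splits that part all 3 shared experiments are too few for a share under 0.05, and the highest other among them gave 20 and 10. The split with 20 exchanges the libraries of each of the 3 shared experiments, so it nearly repeats the comparison of dark LADL with empty-target cells with its sign turned, and its 20 pixels were all lower. The same exchange gave 2 pixels for lit LADL against empty-target cells, and the remaining 6 splits of this kind gave up to 9 and 10.

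Between dark LADL and dark empty-target cells, the block gave 21 pixels in edgeR, 20 of them higher in LADL cells and 15 in the Klf4 region. The tables argue against a library-wide contrast shared by all high pixels. In 210 uncalled pixels matched on their empty-target value the median paired log2 difference was -0.029 ± 0.24 (SD), against 0.58 in the called ones, a ratio of -0.050. The match did not cover the share of the most abundant fragment pair, which was lower in the matched pixels. A library-wide shift of pixels dominated by 1 pair therefore stays open. Over-amplified single fragment pairs may account for part of the fold: 1 pair held a median of 60.2% of the counts of a called pixel against 11.1% in matched pixels, and without it the median log2 fold change went from 0.59 ± 0.30 to 0.16 ± 0.30 (SD, n = 21 pixels), with no call (edgeR 0, with 1065 at an unadjusted p under 0.05; limma on the balanced signal 0). Without that pair 6 of the 21 kept a fold of the same direction more than 2 SE from 0. In 4 the fold stayed within 1 SE, with a larger SE (median over the 21 pixels 0.16 against 0.10). Pixels were picked for their fold and only 1 pair left out, so such pairs as the whole fold stay open. Noise of single libraries stays open. Outside the fit, 11 of the 21 pixels (52.4%) kept their sign in the 4-h dark LADL and empty-target pair. All 21 were higher in the 4-h lit than dark LADL library, by 0.29 to 0.92. A biological difference in the dark stays open and was not tested further.

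No light difference was detected at Zfp462 with the SE, where lit minus dark LADL cells was -0.028 in counts and 0.24 in the authors' balanced signal (exact permutation p = 0.286, higher in experiments 1, 2 and 3, by 0.12, 0.24 and 1.14, lower in the other 2, and 0.016 without experiment 3). Windows placed beside the true anchors may hide one, and over 121 shifted window pairs the difference ran from -0.32 to 0.26, with 0 pairs past the threshold and 0.984 as the smallest adjusted p of those higher in the light (exact permutation tests, with 3 pairs lower and 0 higher at an unadjusted p under 0.05). A missed threshold excludes nothing while some shifts lie above 0, so this stays open. Counting error gives an expected spread of 0.23 between the 5 paired differences against an observed 0.29, a ratio of 0.800, which 5 pairs are too few to decide. An absence of any effect of light on the contact of Zfp462 with the SE also stays open, as no test here can show it.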
